A study of Mus musculus with 16 samples.

How the data were processed

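RNA from tumours of B16F10-GP cells was measured in 16 libraries, 4 in each of 4 treatment groups. Per the labels' protocols, the RNA was prepared by transcriptome capture, which enriches fragments with probes against coding genes, and sequenced on an Illumina instrument. The submitters' processing notes name STAR 2.4.1a as a tool, with featureCounts, edgeR and the mouse genome build mm10. Per the file headers, featureCounts 1.6.0 counted fragments of read pairs over annotated exons, with no strand option given. The deposited values are whole-number counts of fragments per gene, with no normalization. Because the counting used no strand, fragments of a gene and of an antisense or overlapping partner cannot be told apart, and genes with near-identical copies (H2-Q6 and H2-Q7, the globin genes, pseudogenes such as Rpl35a-ps5) have uncertain counts.

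The table held 46078 genes, of which 45143 had a symbol. Coordinates are those of the deposited table in mm10, counted from 1. The 37 mitochondrially encoded genes had 0 counts in the 16 libraries, so the list of mitochondrially encoded genes fixed for this work had 0 of 13 members tested. Total counts per library ranged from 6994198 to 40799942 and summed to 462100861. A count of 0, taken as fewer than 3 counts, allows up to 0.0735 CPM, a count scaled to library size in the deepest library and up to 0.429 CPM in the shallowest. These limits cover counting error only, since the reads carry no molecular identifiers.

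Groups were read from the sample titles. The groups, the comparisons, the tests, the gene lists, the rule for named genes and most of the other settings below were fixed before the data were examined. All 16 libraries entered 1 model of group means in edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM scaling and the robust quasi-likelihood test. The test was two-sided, with Benjamini-Hochberg adjustment over 16101 tested genes and a threshold of 0.05. The contrasts tested were these: 5 Gy against untreated, QH-II-066 against untreated, 5 Gy with QH-II-066 against untreated, against 5 Gy and against QH-II-066, and the interaction of radiation and drug. The interaction is the log2 difference of the combined group from 5 Gy, minus that of QH-II-066 from untreated. Standard errors (SE) of log2 fold changes come from the same model, and levels are CPM with TMM scaling, as mean ± SD over 4 libraries.

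Of 37 gene lists, 36 had tested members and were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. The lists covered T cells, CD8 and cytotoxic cells, NK cells, B cells, plasma cells, macrophages and monocytes, neutrophils, dendritic cells, regulatory T cells, immune checkpoints, endothelial cells, fibroblasts and matrix, skeletal muscle, skin epithelium, adipocytes, erythroid cells and melanocyte pigmentation. The others covered p53 targets, the type I interferon response, the interferon gamma response, MHC class I and MHC class II presentation, chemokines, TNF and NF-kB signalling, mitosis, DNA replication, DNA damage repair, apoptosis regulators, and necroptosis and pyroptosis. The rest were GABA-A receptor subunits, GABA handling and receptor anchoring, the unfolded protein and integrated stress response, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, immediate early genes and the TGF-beta response. Each list was tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. A list score per library is the mean log2 CPM (prior count 2) of the tested members, and groups were compared by a two-sided exact permutation test, whose smallest possible p for 4 against 4 is 0.0286.

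The genes named in each comparison were those with the 10 highest and 10 lowest fold changes among genes past the threshold with a mean log2 CPM of at least 1, or the 5 with the smallest p where no gene passed. Up to 4 members with the smallest adjusted p were added from each list that was called or discussed, and 15 fixed genes were looked up in every comparison, 1 of which is not reported here.

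The results were also computed with RLE scaling, DESeq2 1.42.0, limma-voom with sample weights, no filter and a stricter filter on low counts, a fit of the compared groups alone, the replicate number as a block, the skeletal muscle score as a covariate, an adjusted p under 0.1, each library left out in turn, a median in place of the mean in list scores, and untreated controls split between comparisons that share them. After the data had been seen, 4 settings were added: a fit without the 5 libraries that held skin transcripts, the skin score as a covariate, the gene length slope as a covariate, and both of these together. The gene length slope is the slope, over genes with a mean log2 CPM above 3, of a library's deviation in log2 CPM on log2 gene length, a measure that can follow RNA quality. No library was left out of the main analysis.

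The edgeR step was tested on simulated data for 5 Gy against untreated, over 15850 genes drawn from the means and sizes of the real libraries. It recovered 55% of 100 genes changed 2-fold and 87% of 100 genes changed 4-fold, and 6 unchanged genes were among its 148 calls. Of random unchanged lists, 0.5% had a camera p under 0.05. The simulated genes were drawn independently, without co-expression or tissue differences between libraries. These rates therefore do not carry over to co-expressed lists or to the real libraries. The biological coefficient of variation of the real libraries was 0.361.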

Results

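Tumours formed by B16F10-GP cells were profiled by RNA sequencing. B16F10 is a pigmented melanoma line from a C57BL/6 mouse, and the cells were implanted with Matrigel on the flanks of female mice of that strain. The study concerns the enhancement of GABA-A receptors, chloride channels gated by the transmitter GABA, in melanoma cells given together with radiation. The control samples are labelled untreated, while the protocol describes mice given vehicle, and the pair was taken here as the same group. Mice of the 5 Gy group had a single 5 Gy dose of X-rays to the right flank on day 10. Mice of the QH-II-066 group were injected intraperitoneally with 10 mg/kg of QH-II-066, a compound known by this code name, each day for 7 days from day 10. The combined group was irradiated in the morning and first given the drug that evening. The labels do not state which flank's tumour was profiled, nor that the 4 libraries of a group came from separate mice, so the p-values measure the spread between these samples, which may be partly technical.

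Total counts were 25017744 to 31680098 fragments in the untreated libraries, 26045343 to 29964394 after 5 Gy and 23035634 to 38114306 after QH-II-066. They were 6994198 to 40799942 in the combined group, where replicate 4 was the shallowest of the 16. Correlations of log2 CPM within groups lay between 0.899 and 0.985. Each library was counted as 1 sample.

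Transcripts of tissues next to the tumour varied between libraries. The score of the skin epithelium list (keratins such as Krt5, Krt10 and Krt14, which form the filaments of keratinocytes) was 3.67 or higher in 5 libraries, namely 5 Gy replicates 2 and 4 and replicates 2, 3 and 4 of the combined group, and -0.66 or lower in the other 11. The 5 with a score above 0 are called the libraries with skin transcripts below, although keratins were counted at low levels elsewhere. Krt5 stood at 343 ± 407 CPM in the 5 Gy group, at 0.495 ± 0.991 CPM after QH-II-066 and at 0.0835 ± 0.167 CPM in the untreated group (SD, n = 4 each). The skeletal muscle score was 3.72 ± 3.88 after 5 Gy, 3.15 ± 3.13 in the combined group, 1.15 ± 3.39 after QH-II-066 and 0.96 ± 2.01 in untreated tumours (mean log2 CPM, SD, n = 4). The adipocyte score was 3.42 ± 0.73 after 5 Gy and 0.02 ± 1.88 in untreated tumours. The gene length slope was 0.109 ± 0.112 after 5 Gy and 0.0676 ± 0.175 in untreated tumours, and it was -0.0881 ± 0.158 after QH-II-066 and -0.0883 ± 0.120 in the combined group.

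The comparison of 5 Gy with untreated tumours asked what a single dose of radiation alone did. Genes of fibroblasts and of the collagen matrix they secrete rose strongly, and several genes of macrophages rose with them. Col1a1, which encodes a chain of type I collagen, went from 152 ± 19 to 768 ± 325 CPM (SD, n = 4 each), a log2 fold change of 2.33 ± 0.38 (SE; edgeR adjusted p = 0.0227). Col3a1, the chain of type III collagen, went from 187 ± 74.2 to 1074 ± 360 CPM, a log2 fold change of 2.52 ± 0.43. Mrc1, the mannose receptor of tissue macrophages, rose by 2.05 ± 0.33 from 22.7 ± 2.73 to 94.1 ± 26.1 CPM, and Cd163, the macrophage receptor for haemoglobin bound to haptoglobin, rose by 3.61 ± 0.58 from 1.70 ± 0.54 to 20.7 ± 14.7 CPM (edgeR adjusted p = 0.0227 for both). In the mm10 build, Col1a1 (ENSMUSG00000001506) lies on the plus strand of chromosome 11 at 94936224 to 94953042, and Cd163 (ENSMUSG00000008845) on the plus strand of chromosome 6 at 124304651 to 124330527.

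The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 202 genes higher and 1 lower of 16101 tested. DESeq2 called 1180 higher and 44 lower, and limma-voom with sample weights called 703 higher and 87 lower. Each of the 4 irradiated libraries lay above each of the 4 untreated ones in 5.97% of the tested genes, where chance gives 1.43% on average over regroupings. Because genes move together, a single grouping can lie well above that average, and the share was not computed for other splits. Of the 202 genes 199 had each irradiated library above each untreated one, which their selection on these libraries largely fixes. The gene that fell was 4632404H12Rik (ENSMUSG00000042579, minus strand of chromosome 3, 89767511 to 89773240), from 12.5 ± 1.91 to 7.86 ± 0.68 CPM, a log2 fold change of -0.66 ± 0.15 (edgeR adjusted p = 0.0457). The count of higher genes rested on single libraries. It was 0 without 5 Gy replicate 2, and 0 without untreated replicate 1, 2 or 3. It was 101 without 5 Gy replicate 4, 368 without 5 Gy replicate 1 and 731 without 5 Gy replicate 3. All 203 called genes kept their sign in each of these fits, with a median log2 fold change between 2.06 and 2.42. Their selection on the same libraries largely fixes that sign, so it is no sign of robustness. With the skeletal muscle score as a covariate 2 genes were higher. In settings added after the data had been seen, 22 genes were higher without the libraries with skin transcripts and 14 with the skin score as a covariate. The 22 were all among the 203, which were called in part on the same libraries. That fit leaves 2 libraries of 5 Gy, so a lost call can come from fewer libraries as well as from skin.

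Fibroblast and matrix genes formed the list with the smallest camera p, although the medians of the skin, muscle and adipocyte lists were larger. Of its 15 tested members 12 rose, 14 when adjusted over the list alone, and the median log2 fold change was 2.04 (camera adjusted p = 1.5e-32; adjusted p = 0.0299 with an estimated correlation). Besides the collagens, the members that rose included Pdgfra, the receptor for platelet-derived growth factor on fibroblasts (2.53 ± 0.44, from 3.37 to 19.4 CPM), Mmp2, a secreted gelatinase (1.82 ± 0.29, from 14.7 to 51.9 CPM), and Dcn and Lum, proteoglycans that bind collagen fibrils (2.83 ± 0.56 and 3.04 ± 0.66). Postn, a matricellular protein, rose by 2.14 ± 0.42, Fbn1, the microfibril protein fibrillin, by 2.04 ± 0.36, and Thy1, a surface marker of fibroblasts, by 1.4 ± 0.31. The score of the list was 6.53 ± 0.41 after 5 Gy and 4.60 ± 0.36 in untreated tumours (n = 4 each, exact permutation p = 0.0286, the smallest possible; adjusted p = 0.114 over 36 lists). Skin, muscle and adipocyte scores moved the same way as this list. Without the libraries with skin transcripts, Col1a1 had a log2 fold change of 2.50 ± 0.37 (adjusted p = 0.0477) and Col3a1 2.68 ± 0.39, and Mmp2 and Pdgfra also stayed called. Dcn at 2.34 ± 0.48 (adjusted p = 0.114), Lum at 2.43 ± 0.66 (0.281) and Postn at 2.42 ± 0.41 (0.0773) no longer passed there. Nor did Fbn1 at 2.14 ± 0.38 (0.0817) and Thy1 at 1.07 ± 0.35 (0.461), with 2 libraries of 5 Gy left. Postn and Fbn1 lay no lower there than in the main fit, while Dcn, Lum and Thy1 lay lower. With the muscle score as a covariate Col1a1 was at 2.29 ± 0.40 and missed the threshold (adjusted p = 0.0577).

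**Figure D1:**
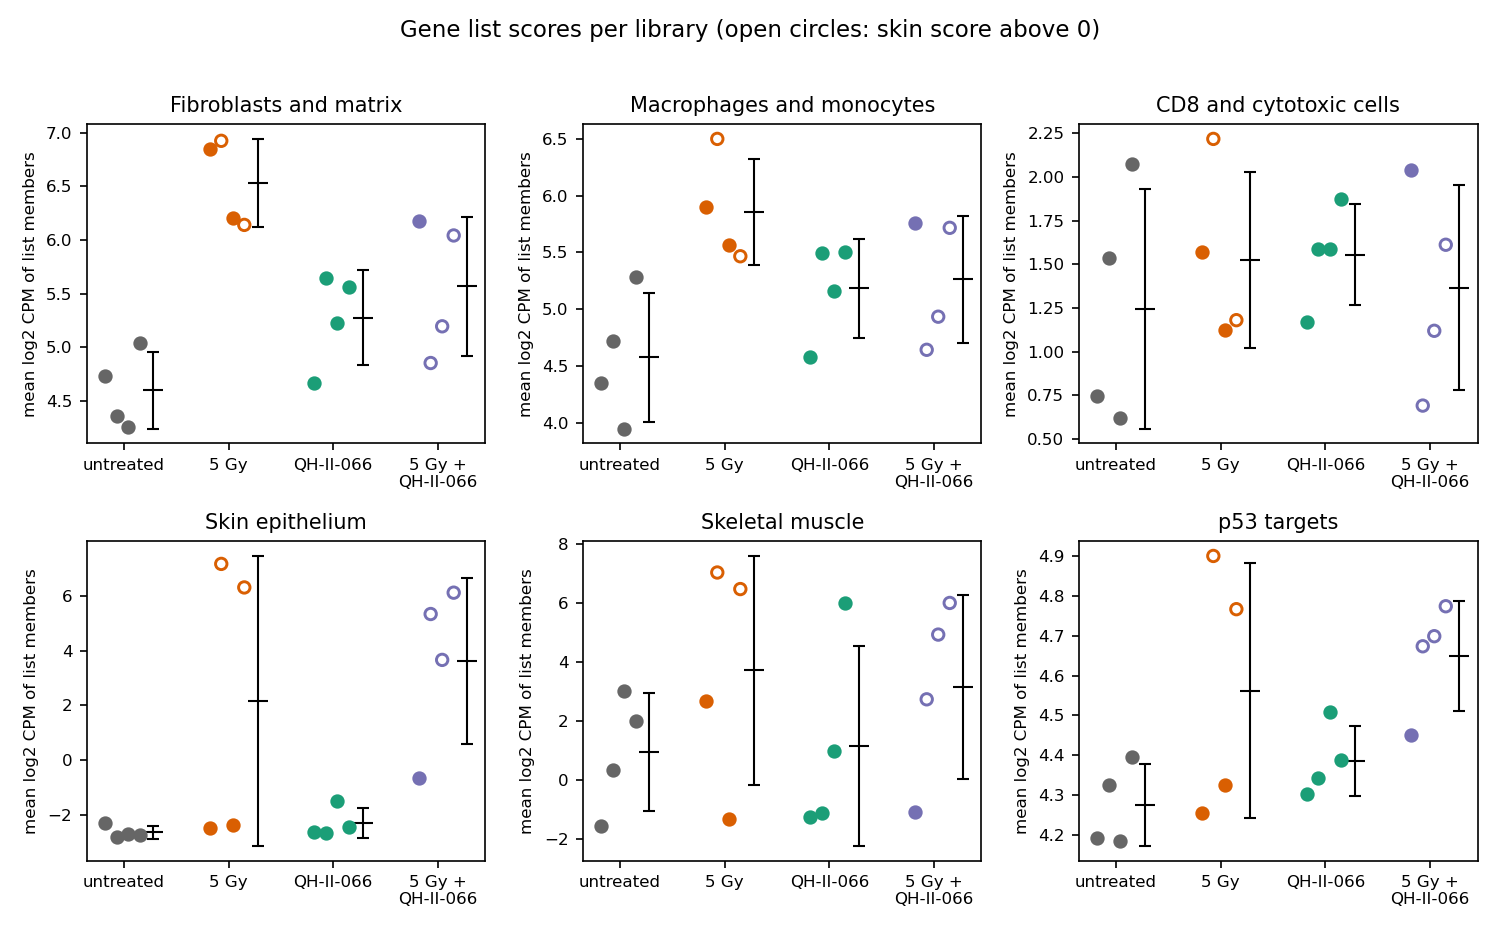
Mean log2 CPM of 6 gene lists in each of the 16 libraries, by treatment group; points are libraries, bars are mean and SD, and open circles are the 5 libraries with a skin score above 0. The fibroblast and matrix score averages 6.53 after 5 Gy and 4.60 in untreated tumours, with no overlap between those groups, while the CD8 and p53 scores overlap.

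Genes of macrophages and monocytes had a median log2 fold change of 1.11, and all 16 tested members were above 0 (camera adjusted p = 2.3e-16; adjusted p = 0.208 with an estimated correlation). Mrc1, Cd163 and Lyz2, the lysozyme of myeloid cells, passed the test over all genes, and 10 members passed when adjusted over the list alone. Lyz2 rose by 1.29 ± 0.27, from 229 ± 78.1 to 558 ± 155 CPM. Csf1r, the receptor for the growth factor that maintains macrophages, was at 1.46 ± 0.35 and just missed the threshold (edgeR adjusted p = 0.0517). Mrc1 at 1.94 ± 0.29 and Cd163 at 2.96 ± 0.36 were still called without the libraries with skin transcripts, but with the muscle score as a covariate both missed the threshold (1.92 ± 0.34 and 3.09 ± 0.52, adjusted p = 0.0577 and 0.0519). Without the skin libraries Lyz2 was at 1.17 ± 0.32 and not called (adjusted p = 0.294).

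Of 13 genes of the TGF-beta response, 4 rose, also 4 when adjusted over the list alone, with a median of 0.76 (camera adjusted p = 9.3e-08; adjusted p = 0.165 with an estimated correlation). They were Ltbp2, which binds fibrillin (2.14 ± 0.46), Bmp1, the protease that trims procollagen (0.98 ± 0.21), and Acta2 and Tagln, contractile proteins of myofibroblasts and smooth muscle (1.18 ± 0.27 and 1.23 ± 0.25). Tek, the angiopoietin receptor, rose by 1.94 ± 0.43 and was the endothelial gene called among 13, with 5 called when adjusted over the list alone (median 0.58; camera adjusted p = 4.6e-05; adjusted p = 0.208 with an estimated correlation). Ccr7, which guides dendritic cells to lymph nodes, rose by 1.67 ± 0.38 and was the dendritic cell gene called among 12, with 4 over the list alone (median 0.89; camera adjusted p = 2.9e-05; adjusted p = 0.208 with an estimated correlation). Cxcl12, a chemokine made by stromal cells, rose by 2.03 ± 0.34, from 12.8 ± 5.62 to 52.2 ± 4.95 CPM, as the gene called among 23 chemokines, with 4 over the list alone (median 0.51; camera adjusted p = 8.6e-07; adjusted p = 0.269 with an estimated correlation). Klf4 and Egr2 rose by 2.78 ± 0.59 and 1.66 ± 0.36 among 16 immediate early genes, 3 of which passed when adjusted over the list alone (median 0.35; camera adjusted p = 5.6e-05; adjusted p = 0.208 with an estimated correlation). Without the libraries with skin transcripts Klf4, a transcription factor also abundant in epidermis, was at 1.28 ± 0.45 and Egr2 at 0.79 ± 0.28 (adjusted p = 0.548 and 0.541). Of the other genes of this paragraph none passed there either, with Ltbp2 at 2.56 ± 0.43, Bmp1 at 1.09 ± 0.20, Acta2 at 0.85 ± 0.34, Tagln at 0.95 ± 0.28, Tek at 1.68 ± 0.50, Ccr7 at 1.85 ± 0.44 and Cxcl12 at 1.98 ± 0.33 (adjusted p = 0.0684, 0.0896, 0.71, 0.344, 0.361, 0.191 and 0.0728).

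The 10 genes with the highest fold changes were Anxa8, AI661453, Chl1, Nectin1, Sfrp1, C6, Fst, Ephb3, Tmem45a and Cd163. Chl1, a cell adhesion molecule of the L1 family, rose by 4.33 ± 0.57 from 0.375 ± 0.186 to 7.63 ± 4.41 CPM and had the smallest adjusted p (0.0162, edgeR). Sfrp1, a secreted antagonist of Wnt ligands, rose by 4.11 ± 0.72 and Fst, which binds and blocks activin, by 3.77 ± 0.63. C6, a component of the complement membrane attack complex, rose by 3.90 ± 0.88, and Nectin1, an adhesion protein, by 4.18 ± 0.91. Ephb3, an ephrin receptor, rose by 3.77 ± 0.70, Tmem45a by 3.74 ± 0.82 and AI661453 by 4.50 ± 1.01. Anxa8, an annexin of stratified epithelia, had a log2 fold change of 9.87 ± 2.19, but its level was 139 and 100 CPM in the 5 Gy libraries with skin transcripts and 1.03 and 0.439 CPM in the others. Without the skin libraries Chl1 was still called at 3.39 ± 0.45 and Fst at 2.97 ± 0.45 (edgeR adjusted p = 0.0477 for both), as was Cd163. Anxa8, AI661453, Nectin1, Sfrp1, C6, Ephb3 and Tmem45a were not among the genes called there. Nectin1 was at 23.3 and 10.7 CPM in the 5 Gy libraries with skin transcripts and 1.42 and 1.42 CPM in the others. In the same order AI661453 was at 20.2 and 4.95 against 0.783 and 0.574 CPM, and Tmem45a at 44.9 and 28.5 against 5.52 and 6.08 CPM. Ephb3 was at 14.6 and 4.95 against 3.13 and 1.15 CPM, while Sfrp1 and C6 overlapped between these libraries.

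**Figure D2:**
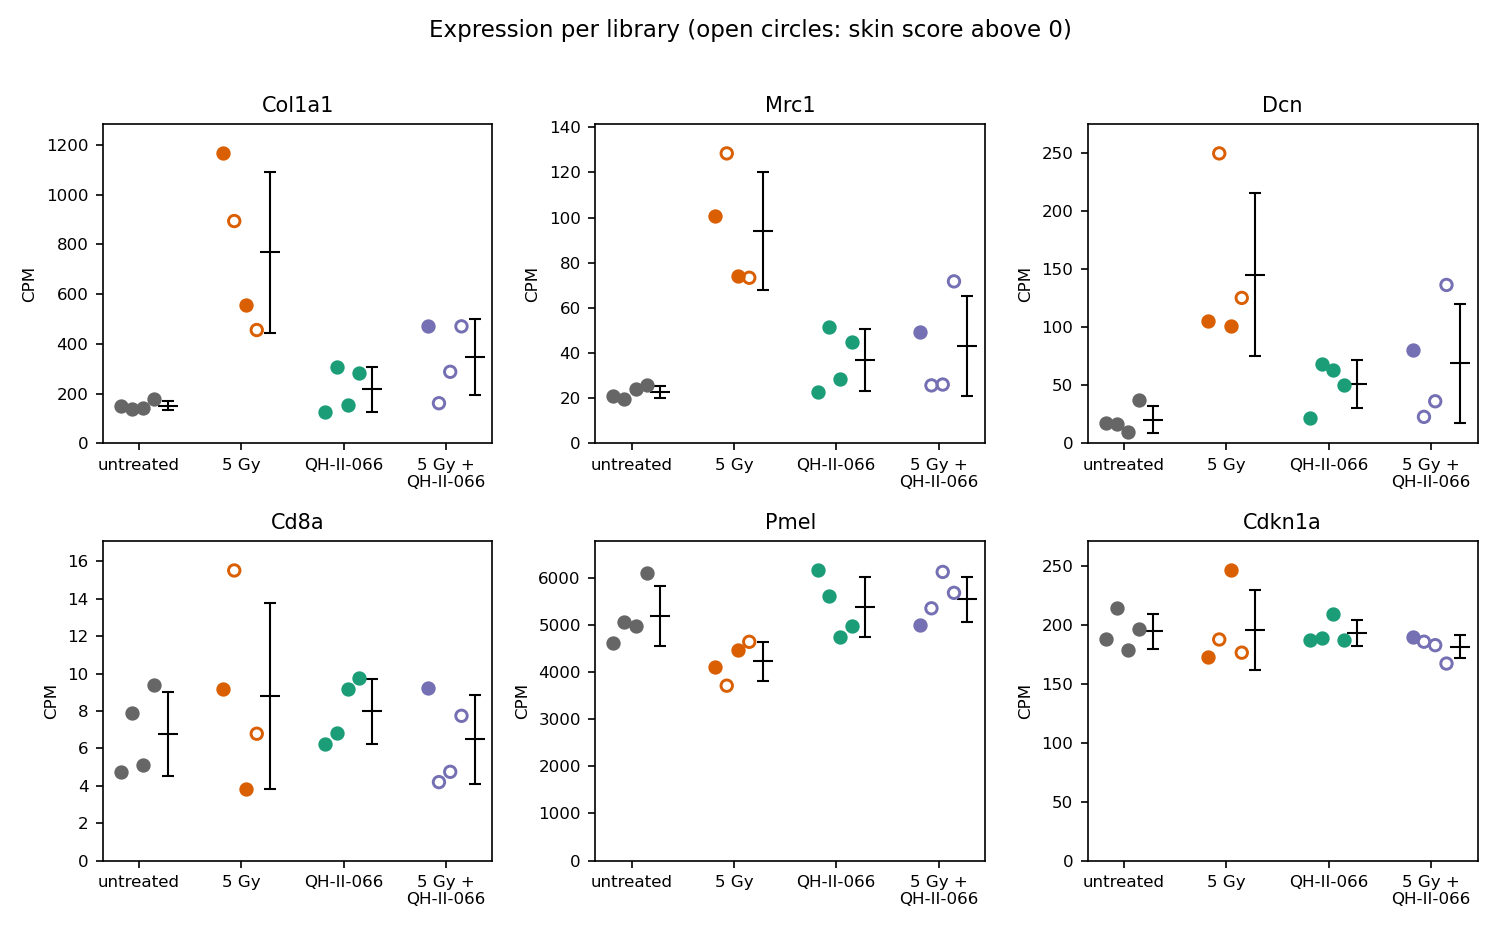
CPM of Col1a1, Mrc1, Dcn, Cd8a, Pmel and Cdkn1a in each library by treatment group, on linear axes from 0; points are libraries, bars are mean and SD, and open circles mark the 5 libraries with skin transcripts. Col1a1 averages 768 CPM after 5 Gy against 152 CPM in untreated tumours, while Cdkn1a averages 195 and 194 CPM.

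Melanocyte genes lay slightly lower after 5 Gy. The 15 tested genes of pigmentation all had a negative log2 fold change, with a median of -0.35 (camera adjusted p = 3.3e-05; adjusted p = 0.208 with an estimated correlation), although 0 passed singly or when adjusted over the list alone. Pmel, the fibril protein of melanosomes, was at 4236 ± 413 CPM against 5199 ± 641 CPM (log2 fold change -0.30 ± 0.13, edgeR adjusted p = 0.31), and Mc1r, the melanocortin receptor, was at -0.42 ± 0.14 (adjusted p = 0.122). Lists of dividing cells and of biosynthesis shifted down by less: DNA replication had a median of -0.22 (camera adjusted p = 0.00151), mitosis -0.13 (0.0202), DNA damage repair -0.16 (0.0205), the unfolded protein and integrated stress response -0.23 (0.00151) and nuclear oxidative phosphorylation -0.22 (0.00411). None of these held with an estimated correlation, where the adjusted p was 0.477, 0.477, 0.567, 0.321 and 0.477, and 0 of their members passed when adjusted over the list alone. In the fit without the libraries with skin transcripts mitosis, DNA damage repair and nuclear oxidative phosphorylation were not called (camera adjusted p = 0.445, 0.0711 and 0.2). Mki67, a marker of dividing cells, had a log2 fold change of -0.20 ± 0.12 (edgeR adjusted p = 0.508).

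By fry 7 lists passed for 5 Gy, and 0 lists passed in any other comparison. They were fibroblasts and matrix (adjusted p = 0.00505), the TGF-beta response (0.0143) and immediate early genes (0.0436). The others were macrophages and monocytes, dendritic cells, endothelial cells and melanocyte pigmentation (0.0414 each). Lists of lymphoid and granulocytic cells were shifted up under the preset correlation, with 0 members past the test over all genes. Medians were 0.50 for T cells (camera adjusted p = 0.00232), 0.51 for NK cells (0.0272), 0.55 for plasma cells (0.0272), 0.96 for regulatory T cells (0.00145), 0.84 for neutrophils (0.00373), 0.54 for immune checkpoints (0.00609) and 0.40 for TNF and NF-kB signalling (0.0013). With an estimated correlation the adjusted p was 0.477, 0.477, 0.314, 0.269, 0.23, 0.477 and 0.31, in the same order. When adjusted over the list alone, 1 gene passed among plasma cells, regulatory T cells and neutrophils each and 2 among immune checkpoints, one of them Ctla4, an inhibitory receptor of T cells (1.21 ± 0.32; edgeR adjusted p = 0.0685 over all genes). The lists of T cells, NK cells, plasma cells and immune checkpoints were no longer called without the libraries with skin transcripts (camera adjusted p = 0.134, 0.0711, 0.0711 and 0.053). CD8 and cytotoxic cells were not called (median 0.33, camera adjusted p = 0.237), nor were B cells (0.10, 0.552). Cd8a, the co-receptor of cytotoxic T cells, was at 8.82 ± 4.97 against 6.78 ± 2.24 CPM (log2 fold change 0.38 ± 0.38, edgeR adjusted p = 0.684), Gzmb, a killing protease of these cells, at -0.36 ± 0.44 (0.732), and Ifng at 0.67 ± 0.53 (0.613).

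The classical p53 targets were not called after 5 Gy. Cdkn1a, the p53-induced inhibitor of the cell cycle, was at 195 ± 34.3 CPM against 194 ± 15.2 CPM (log2 fold change 0.01 ± 0.11, edgeR adjusted p = 0.977), and Mdm2, which degrades p53, was at -0.08 ± 0.13 (0.811). The median of 26 p53 targets was -0.04 and their mean 0.43 (camera adjusted p = 0.457), and the 1 member passing when adjusted over the list alone was Perp, a desmosome protein that belongs to the skin list as well (7.29 ± 1.89). In the combined group the p53 score was 4.65 ± 0.14 against 4.28 ± 0.10 in untreated tumours, with no overlap (n = 4 each, exact permutation p = 0.0286; adjusted p = 0.257 over 36 lists), and the 3 libraries with skin transcripts were its highest. The type I interferon response (median 0.06, camera adjusted p = 0.33), the interferon gamma response (0.09, 0.557), MHC class I (-0.06, 0.998) and class II presentation (0.15, 0.469), apoptosis regulators (-0.05, 0.722), necroptosis and pyroptosis (0.17, 0.16), hypoxia and glycolysis (-0.10, 0.658) and erythroid cells (0.41, 0.114) were not called. Cxcl9 and Cxcl10, interferon-induced ligands that attract T cells, were at 0.21 ± 0.27 and 0.00 ± 0.32, and Cd274, which encodes the checkpoint ligand PD-L1, at 0.33 ± 0.27 (edgeR adjusted p = 0.745, 0.997 and 0.623).

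Lists of neighbouring tissues were shifted up as well. The skin epithelium list had a median of 10.76 over 13 genes (camera adjusted p = 2.1e-07; adjusted p = 0.291 with an estimated correlation), skeletal muscle 4.44 over 17 genes (8.8e-05; 0.477 with an estimated correlation) and adipocytes 2.83 over 10 genes (8.6e-07; 0.269 with an estimated correlation). None of these genes passed the test over all genes, and when adjusted over the list alone 13 skin genes and 0 of the muscle and adipocyte genes did. Acta1, the actin of skeletal muscle, was at 383 ± 436 against 14 ± 15.4 CPM (log2 fold change 4.77 ± 2.46, edgeR adjusted p = 0.394). In the fit without the skin libraries the muscle list had a median of -0.12 and the adipocyte list stayed above the rest (camera adjusted p = 1e-06).

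Subunits of the GABA-A receptor, the stated target of the study, included 3 genes with enough counts to be tested. Gabra5 and Gabra6, which encode the alpha 5 and alpha 6 subunits, had 0 counts in the 16 libraries. Whether the capture probes covered these genes is not known, so 0 counts do not show that they were silent. Gabra3 was at 1.36 ± 0.76 CPM after 5 Gy, 0.857 ± 0.447 CPM after QH-II-066, 1.25 ± 1.16 CPM in the combined group and 0.238 ± 0.163 CPM in untreated tumours (log2 fold change for 5 Gy 2.48 ± 0.84, edgeR adjusted p = 0.14). The subunit list was not called for 5 Gy (median 0.65, camera adjusted p = 0.101; 1 member when adjusted over the list alone, Gabra3), although its score was higher in each 5 Gy library than in each untreated one (-0.64 ± 0.15 against -1.65 ± 0.56, n = 4 each, exact permutation p = 0.0286; adjusted p = 0.114 over 36 lists). In settings added after the data had been seen the list was called, at a camera adjusted p of 0.028 without the libraries with skin transcripts and 0.0383 with the skin score as a covariate. The first of these tested 5 subunits in place of 3, so it was not the same set. With the muscle score as a covariate the list was not called (camera adjusted p = 0.0554). All 19 subunits had a mean under 1 CPM. Not called for 5 Gy was GABA handling and receptor anchoring (median -0.01, camera adjusted p = 0.998).

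QH-II-066 was set against untreated tumours to ask what the drug alone did. No gene passed the test, and the genes with the smallest p included Tagln, an actin-binding protein of smooth muscle and myofibroblasts, which was at 25.9 ± 9.80 against 12.3 ± 1.67 CPM (log2 fold change 1.07 ± 0.25, edgeR adjusted p = 0.546). Adamts8, a secreted metalloprotease, was at 4.99 ± 1.1, Pcsk5, a proprotein convertase, at 2.04 ± 0.46, Gm26615 at 3.23 ± 0.77 and Hoxc9, a homeobox gene, at 2.16 ± 0.53, all with the same adjusted p. Adamts8 and Gm26615 rested on few fragments. Adamts8 lay at 0 to 0.0334 CPM in untreated libraries and 0.0330 to 0.637 CPM after QH-II-066, and Gm26615 at 0.0320 to 0.0769 and 0.0659 to 1.14 CPM. The edgeR count was 0, with 1316 genes at an unadjusted p under 0.05 (506 higher and 810 lower). DESeq2 called 13 higher and 3 lower, and limma-voom with sample weights called 1875 higher and 2747 lower.

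Under the preset correlation 9 lists were shifted up and 2 down by QH-II-066, and none held with an estimated correlation, where the smallest adjusted p was 0.801. Adipocyte genes had a median of 3.62 (camera adjusted p = 8e-08), and all 10 passed when adjusted over the list alone. Fabp4, a lipid carrier of fat cells, was at 215 ± 179 against 43.7 ± 26.4 CPM (2.30 ± 0.57, edgeR adjusted p = 0.546), and the adipocyte score reached 6.01 in replicate 3. That score was 3.06 ± 2.77 against 0.02 ± 1.88 with overlap between the groups (SD, n = 4 each, exact permutation p = 0.2; adjusted p = 0.554). Of 36 list scores, 0 reached an exact permutation p under 0.05 for QH-II-066 against untreated. Fibroblasts and matrix had a median of 0.69 (2.3e-05), macrophages and monocytes 0.49 (2.5e-05), chemokines 0.24 (0.00199), MHC class II presentation 0.39 (0.0143), MHC class I presentation 0.25 (0.0199) and dendritic cells 0.44 (0.0391), with 0 members of these passing even when adjusted over the list alone. DNA damage repair had a median of -0.31 (0.00014) and mitosis of -0.19 (0.00323). Nuclear oxidative phosphorylation at 0.20 and necroptosis and pyroptosis at 0.31 were at an adjusted p of 0.048 each. With the gene length slope as a covariate, added after the data had been seen, nuclear oxidative phosphorylation turned to -0.0451 and was not called. Mrc1 was at 0.70 ± 0.32, Col3a1 at 0.97 ± 0.41, Cd8a at 8.00 ± 1.74 CPM and Mki67 at -0.31 ± 0.12 (edgeR adjusted p = 0.546 for Mrc1, Col3a1 and Mki67). The gene length slope differed between the libraries with and without drug, at -0.0882 ± 0.130 against 0.0882 ± 0.138 (SD, n = 8 each, two-sided exact permutation p = 0.0224). The slope was brought in after the data had been seen, and this test pooled irradiated and unirradiated libraries.

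Both treatments together were compared with untreated tumours. No gene passed. Among the 5 with the smallest p, those that lay higher were Ctsk, a collagen-degrading protease (19.3 ± 7.49 against 7.80 ± 1.74 CPM, log2 fold change 1.31 ± 0.27), P3h4, which takes part in collagen modification (1.4 ± 0.30), and A430106G13Rik (2.36 ± 0.51). Those that lay lower were Sufu, a brake on hedgehog signalling (-0.71 ± 0.15), and Gbe1, the glycogen branching enzyme (-0.78 ± 0.17). Each had an edgeR adjusted p of 0.298. Col1a1 was at 348 ± 151 CPM (1.19 ± 0.37), Cd163 at 6.75 ± 5.99 CPM (1.94 ± 0.55), Mrc1 at 43.2 ± 22 CPM (0.91 ± 0.33) and S100a8, a protein of neutrophils that inflamed epidermis also makes, at 9.01 ± 16.5 against 0.275 ± 0.310 CPM (5.05 ± 1.37). The edgeR count was 0, with 2615 genes at an unadjusted p under 0.05 (1198 higher and 1417 lower). DESeq2 called 190 higher and 16 lower, and limma-voom called 0 of either.

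Of the gene lists 8 were shifted up and 3 down in the combined group against untreated, and none held with an estimated correlation (smallest adjusted p = 0.524). Skin epithelium had a median of 10.35 (camera adjusted p = 4.4e-11; 13 of 13 when adjusted over the list alone), with Krt10 at 131 ± 158 against 0.0936 ± 0.0875 CPM. Fibroblasts and matrix had a median of 1.19 (3.7e-09; 11 of 15 over the list alone), macrophages and monocytes 0.64 (2.5e-05; 5 of 16), neutrophils 0.98 (0.00417; 3 of 9), skeletal muscle 3.01 (0.00163; 0 of 17), immediate early genes 0.33 (0.00073; 0 of 16), chemokines 0.45 (0.00104; 0 of 23) and the TGF-beta response 0.24 (0.0107; 2 of 13). DNA damage repair at -0.36 (0.000105), mitosis at -0.24 (0.00073) and DNA replication at -0.22 (0.00073) were shifted down, as was the gene length slope (-0.0883 against 0.0676), with 0 members passing over the list alone, among them Top2a, the topoisomerase of dividing cells, at -0.39 ± 0.15. With the length slope as a covariate, added after the data had been seen, DNA damage repair was at -0.15, and with skin score and slope together none of these 3 lists was called. The skin score was 3.62 ± 3.03 in this group.

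Fold changes of the 3 comparisons against the same untreated libraries were correlated across genes, which are not independent replicates. The simulations drew each gene independently, without co-expression or tissue differences between libraries. A correlation or covariance above the simulated one is therefore no evidence of a shared response to treatment. For 5 Gy with both treatments Pearson's r was 0.88, where unchanged groups simulated against shared controls gave 0.49. The covariance was 1.39 against a simulated 0.131. These are the groups that hold the libraries with skin transcripts, and without those libraries r was 0.29, with 1 library left in the combined group. From mean log2 CPM per group r was 0.73 with the 4 controls shared, 0.76 with the same 2 controls in both comparisons and 0.57 with 2 different controls in each (0.42 to 0.69). For 5 Gy with QH-II-066 r was 0.49, where simulation gave 0.50, with a covariance of 0.417 against 0.130, an r of 0.45 without the libraries with skin transcripts and, from log2 CPM, 0.55 with the same 2 controls and 0.29 with different ones. For QH-II-066 with both treatments r was 0.52 against a simulated 0.49, with a covariance of 0.385 against 0.130, an r of 0.41 without the libraries with skin transcripts and, from log2 CPM, 0.60 with the same 2 controls and 0.33 with different ones. The 203, 0 and 0 genes called leave no overlap of calls to count.

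The combined group was set against 5 Gy alone to ask what the drug added to radiation. Several of the genes that 5 Gy had raised lay lower with the drug, but no gene passed the test. All 202 genes higher after 5 Gy lay lower here (median -1.01), but they had been chosen for high values in the same 5 Gy libraries, so lower values are no evidence of a drug effect. Mrc1 was at 43.2 ± 22 against 94.1 ± 26.1 CPM (log2 fold change -1.14 ± 0.33), Cd163 at -1.67 ± 0.53, Col1a1 at -1.14 ± 0.37, Col3a1 at -1.26 ± 0.41 and Cxcl12 at -1.20 ± 0.32. The smallest p belonged to Gpr183, an oxysterol receptor that positions immune cells (0.244 ± 0.083 against 1.27 ± 0.44 CPM, -2.28 ± 0.38), Dab2, an endocytic adaptor (-1.14 ± 0.21), Fcgr2b, the inhibitory Fc receptor (-0.77 ± 0.15), Rpl35a-ps5, a ribosomal pseudogene (4.01 ± 0.78), and Gm42970, which had 0 counts in the 5 Gy libraries and 1.33 ± 1.45 CPM in the combined group (edgeR adjusted p = 0.209 for each). Rpl35a-ps5 lay at 0.0675 CPM or lower in the 5 Gy libraries, near the floor. The edgeR count was 0, with 3136 genes at an unadjusted p under 0.05 (1864 higher and 1272 lower), whereas DESeq2 called 75 higher and 48 lower and limma-voom 20 higher and 64 lower.

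Of the lists, 3 were shifted up and 6 down, and none held with an estimated correlation (smallest adjusted p = 0.904). Fibroblasts and matrix had a median of -0.95 (camera adjusted p = 1.9e-07; 7 of 15 lower when adjusted over the list alone), macrophages and monocytes -0.43 (0.00327; 3 of 16), dendritic cells -0.64 (0.0477; 1 of 12), adipocytes -2.11 (0.00763; 0 of 10), TNF and NF-kB signalling -0.29 (0.0419; 1 of 17) and the TGF-beta response -0.44 (0.0438; 0 of 13). Nuclear oxidative phosphorylation had a median of 0.34 (0.000185; 8 of 19 higher over the list alone), melanocyte pigmentation 0.31 (0.0106; 5 of 15) and the unfolded protein and integrated stress response 0.19 (0.0469; 0 of 19). Among these, Mc1r was at 0.49 ± 0.14, Pmel at 0.39 ± 0.13 and Cox7a2, a subunit of cytochrome oxidase, at 0.90 ± 0.27. The adipocyte score was 0.98 ± 1.72 in the combined group, and its gene length slope was lower than that of the 5 Gy group.

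The combined group against QH-II-066 alone asked what radiation added to the drug. The genes with the smallest p were Krt10, a keratin of the upper epidermis (131 ± 158 against 0.248 ± 0.103 CPM), Asprv1, a protease of the stratum corneum (7.72 ± 2.01), Inava (3.14 ± 0.76), Slc10a6 (2.17 ± 0.58) and Gm13110 (1.70 ± 0.41), each at an edgeR adjusted p of 1. Col1a1 was at 0.67 ± 0.36 and Cdkn1a at -0.09 ± 0.11. The edgeR count was 0, with 588 genes at an unadjusted p under 0.05 (446 higher and 142 lower). DESeq2 called 47 higher and 1 lower, and limma-voom called 0 of either.

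In that comparison 5 lists were shifted up and 7 down, and none held with an estimated correlation (smallest adjusted p = 0.184). Skin epithelium had a median of 8.65 (camera adjusted p = 1.8e-25; 13 of 13 when adjusted over the list alone), neutrophils 1.18 (0.000612), immediate early genes 0.30 (0.0016), fibroblasts and matrix 0.33 (0.00113) and skeletal muscle 0.41 (0.00133). Adipocytes were at -2.81 (8e-08), MHC class II presentation at -0.45 (0.00113), the interferon gamma response at -0.27 (0.00148), hypoxia and glycolysis at -0.21 (0.00113), the type I interferon response at -0.18 (0.00967), MHC class I presentation at -0.16 (0.0366) and DNA replication at -0.10 (0.00447). Apart from skin, 0 members of these lists passed when adjusted over the list alone. Without the libraries with skin transcripts, which leaves 1 library of the combined group, the median was 0.19 for the type I interferon response, 0.25 for MHC class I presentation and -6.23 for skeletal muscle, each turned in direction. Limma-voom with sample weights turned fibroblasts and matrix to -0.27 and DNA replication to 0.0453, and called neither.

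The interaction asked whether the effect of both treatments differed from the sum of each on the log2 scale. Fibroblast and macrophage genes lay below that sum: Fbn1 was at -2.08 ± 0.50, Col3a1 at -2.23 ± 0.58, Mrc1 at -1.84 ± 0.46 and Cd163 at -2.80 ± 0.76, none past the test over all genes (edgeR adjusted p = 0.445, 0.481, 0.471 and 0.481). The smallest p belonged to Gpr183 (-2.92 ± 0.52), Chl1 (-3.94 ± 0.74), Pcsk5 (-3.31 ± 0.63), Npl, which degrades sialic acid (-2.49 ± 0.49), and Peli2, a ubiquitin ligase of innate immune signalling (-3.45 ± 0.70), each at an adjusted p of 0.445. The edgeR count was 0, with 1121 genes at an unadjusted p under 0.05 (251 higher and 870 lower). DESeq2 called 3 higher and 56 lower, and limma-voom 54 higher and 438 lower.

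Of the lists, 15 had a negative and 3 a positive interaction under the preset correlation, and none held with an estimated correlation. The median was -1.66 for fibroblasts and matrix (camera adjusted p = 7.2e-21; adjusted p = 0.142 with an estimated correlation), where 13 of 15 genes were lower when adjusted over the list alone, and -0.93 for macrophages and monocytes (1e-12; adjusted p = 0.333 with an estimated correlation), where 5 of 16 were. The adipocyte list had a median of -5.91, with 10 of 10 lower over the list alone (1.4e-15; adjusted p = 0.242 with an estimated correlation). The 202 genes higher after 5 Gy all had a negative interaction, with a median of -1.93, but they were chosen on libraries that enter this term and are not independent evidence of its direction. In the comparison of the combined group with QH-II-066, which shares no library with that choice, 159 of the 202 were above 0, with a median of 0.33. The skin score was above 0 in 2 of the 5 Gy libraries behind that choice, in 3 of the combined group and in 0 of QH-II-066, so shared skin can lift this number.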

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

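The tests of skin tissue were chosen after the results had been seen. The skin epithelium score was above 0 in 5 of 8 irradiated libraries and in none of the 8 unirradiated ones. Induction of these genes in every irradiated tumour by 5 Gy would place all 8 irradiated libraries above the highest unirradiated one. Of the 8, 6 lay above it, and 5 Gy replicates 1 and 3 did not. This count cannot decide, since the labels do not state which flank's tumour was profiled. Those replicates may come from a flank that was not irradiated. Pieces of skin taken along with the tumour stay open: 100% of the 13 tested skin genes were higher in each of those 5 libraries than in all 11 others, but the libraries had been picked by the mean of these genes. Chance placement of skin stays open too, because the pattern had been picked out of many lists before its two-sided Fisher exact p of 0.0256 (n = 8 and 8) was computed.

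The tests of the radiation pattern were chosen after the results. Fibroblast, matrix and macrophage genes were higher after 5 Gy. In lists fixed before the data were examined, the median log2 fold change without the libraries with skin transcripts was 2.14 against 2.04 with them for fibroblasts and matrix, and 0.75 against 1.11 for macrophages and monocytes. Random lists reached 0.57 and 0.32, but they were drawn gene by gene without co-expression, so they cannot decide. The fibroblast median did not fall, which argues against epidermis as its whole cause, with 2 libraries of 5 Gy left. The macrophage median fell, and epidermis as a cause of it stays open. The prediction for a lower share of melanoma cells was that 11 lists of immune, endothelial and fibroblast cells rise alike. Their changes differed (SD 0.46 between lists, exact permutation p = 0.0286, n = 4 each), from 0.28 for CD8 and cytotoxic cells to 1.28 for macrophages and 1.93 for fibroblasts. This p cannot decide, since the prior count compresses changes of lists near the floor, such as neutrophils and NK cells (untreated scores -0.62 and -0.27). Lists with untreated scores from 4.03 to 4.60 also differed, with 0.57 for endothelial cells, but were not tested alone. All 11 changes were above 0 and pigmentation genes were lower. A lower share of melanoma cells thus stays open, as do dermis or fat without epidermis and a growth of tumour stroma.

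The regrouping of libraries was chosen before the results, except for the unadjusted count of 5 Gy. In the 35 ways of splitting the 8 libraries of 5 Gy and untreated tumours into 4 and 4, the real grouping gave 203 genes. It was the 1 split to reach that count, the highest other being 0, and 1 of 35 is the smallest share possible. By the same count, false groupings gave up to 4478 genes for QH-II-066 and 3860 for both treatments, each against untreated. The real groupings gave 0 there. Counts of this size can thus arise from false groupings of such libraries, and chance could not be excluded. At an unadjusted p under 0.05, 5 Gy against untreated gave 2438 genes, 4 of 35 splits gave as many, and the highest other gave 2781. On the same measure QH-II-066 against untreated gave 1316 genes, 8 of 35 splits gave as many, and the highest other gave 6478. Both treatments against untreated gave 2615, with 5 of 35 as many and 6476 the highest other, and against 5 Gy they gave 3136, with 4 of 35 and 3670. Against QH-II-066 they gave 588, with 19 of 35 and 3982, and the interaction gave 1121, with 19 of 100 draws and 6319, so chance could not be excluded in any of these either.

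The checks of single libraries were fixed before the results, and chance gives about 1 in 20 of them. Of 144 sets of 4 scores tested, 3 held a library that stood apart by Dixon's ratio, where 7.2 are expected by chance. These were the plasma cell score of untreated replicate 4 (ratio 0.9004, score 2.52 against 0.64 in the nearest library), the apoptosis score of 5 Gy replicate 4 (0.847, 4.91 against 5.01) and the TGF-beta response score of replicate 2 of the combined group (0.8996, 3.63 against 4.07).

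Gene lists with an interaction of radiation and drug under the preset correlation were tested as fixed before the results. The camera adjusted p was 7.2e-21 for fibroblasts and matrix, 1.4e-15 for adipocytes, 1.02e-12 for macrophages and monocytes, 3.5e-05 for dendritic cells, 7.8e-05 for chemokines, 0.000205 for the TGF-beta response, 0.000901 for endothelial cells, 0.00134 for TNF and NF-kB signalling, 0.00602 for immune checkpoints, 0.00834 for MHC class II presentation, 0.0126 for T cells, 0.0146 for the type I interferon response, 0.0146 for the interferon gamma response, 0.0225 for NK cells and 0.0398 for necroptosis and pyroptosis, all negative. It was 0.000695 for melanocyte pigmentation, 0.00134 for the unfolded protein and integrated stress response and 0.0281 for nuclear oxidative phosphorylation, all positive. With an estimated correlation the smallest adjusted p was 0.142. Without the libraries with skin transcripts, a setting added after the results, which leaves 1 library in the combined group, the median turned to 0.16 for T cells, 0.25 for NK cells, 0.12 for the type I interferon response, 0.16 for the interferon gamma response, 0.18 for MHC class II presentation and 0.25 for necroptosis and pyroptosis.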

How the results depend on the processing

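The 203 genes called for 5 Gy against untreated kept their sign in every setting in which they were tested, which their selection on the same libraries largely fixes. Their number did not hold. Against 202 higher and 1 lower, DESeq2 gave 1180 and 44, limma-voom with sample weights 703 and 87, and an adjusted p under 0.1 776 and 12. The muscle covariate gave 2 higher and 0 lower, the skin covariate 14 and 0, the fit without skin libraries 22 and 0, skin and length slope together 48 higher, and the length slope alone 10 lower. No filter and a fit of the compared groups alone gave 0 lower. Leaving out 1 library gave 0 to 731 higher and 0 to 8 lower. In the other comparisons, with 0 in edgeR and 0 with any library left out, DESeq2 gave 13 higher and 3 lower for QH-II-066, 190 and 16 for both treatments against untreated, 75 and 48 against 5 Gy, 47 and 1 against QH-II-066, and 3 and 56 for the interaction. Weighted limma-voom gave 1875 and 2747 for QH-II-066, 20 and 64 for both against 5 Gy and 54 and 438 for the interaction. The interaction had 1 lower gene with the skin covariate and 1 with skin and length slope. With different controls in each comparison, the correlations of fold changes were 0.29, 0.57 and 0.33, and without skin libraries 0.45, 0.29 and 0.41 (5 Gy with QH-II-066, 5 Gy with both, QH-II-066 with both). The settings that use skin libraries, skin score or length slope were chosen after the results, and apart from weighted limma-voom for QH-II-066 the cause was not tested.

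Some lists turned in direction in camera, which sets a list against all other genes, so that some medians below kept their sign. The skeletal muscle median for 5 Gy was 0.0108 with the muscle covariate, -0.12 without skin libraries, -0.26 with the skin covariate and -0.43 with skin and slope. For QH-II-066 it lay between -1.72, without QH-II-066 replicate 4, and 3.51 with 1 library left out. For both against untreated it was -0.0346, -3.45, -1.28 and -1.04 in the same 4 settings as for 5 Gy, and against QH-II-066 0.0669, -6.23, -3.92 and -4.02. MHC class I presentation lay between -0.17 and 0.29 for 5 Gy with 1 library left out, the highest without untreated replicate 4. It was at -0.22 for both against untreated with skin and slope, where MHC class II was at -0.63, and at -0.20 for both against 5 Gy with the slope and -0.20 with skin and slope. Nuclear oxidative phosphorylation for QH-II-066 was at -0.0451 with the slope and -0.0229 with skin and slope. CD8 and cytotoxic cells were at 0.71 for both against 5 Gy without skin libraries.

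For both against QH-II-066, weighted limma-voom turned T cells to -0.48, macrophages to -0.50, fibroblasts to -0.27, chemokines to -0.30, DNA replication to 0.0453 and DNA damage repair to 0.12. Without skin libraries CD8 cells were at 0.53, NK cells at 0.51, the type I interferon response at 0.19, the interferon gamma response at -0.00359 and MHC class I at 0.25. Hypoxia and glycolysis were at -0.0145 with the skin covariate and -0.0116 with skin and slope, nuclear oxidative phosphorylation at 0.17 with the skin covariate, DNA replication at 0.0187 with skin and slope, and the type I interferon response between -0.33 and 0.0254 with 1 library left out, the highest without QH-II-066 replicate 3. The interaction without skin libraries was 0.16 for T cells, 0.25 for NK cells, 0.12 for type I interferon, 0.16 for interferon gamma, 0.29 for MHC class I, 0.18 for MHC class II and 0.25 for necroptosis and pyroptosis.

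Replicate numbers are shared between groups, but 4 of 16 libraries correlated best with their own number, and 12 of 24 same-number pairs had a correlation above 0.1 (-0.43 to 0.48). With the replicate number as a block, 154 genes were higher and 0 lower for 5 Gy, and 0 passed in the other comparisons. Depth limits the 6994198 counts of replicate 4 of the combined group most, where a count of 0 allows up to 0.429 CPM.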

Other observations

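The gene length slope as a covariate was chosen after the data had been seen, and the other checks of limma-voom before their own results. Weighted limma-voom called 4622 genes for QH-II-066 against untreated where edgeR called 0. With equal weights limma-voom called 0, and with the gene length slope as a covariate the weighted test called 0. Of 35 splits of these libraries 9 gave as many calls, the highest other 6654, so chance could not be excluded. Weights were 0.314 for untreated replicate 4 and 2.94 for QH-II-066 replicate 4, so the calls may come from down-weighting of single libraries along a gradient of RNA length, and a drug effect that follows this gradient cannot be told apart from it.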
